A study of Mus musculus with 10 samples.

How the data were processed

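RNA from prefrontal cortex of wild-type C57BL/6J mice was sequenced in 10 libraries, 5 after hypobaric hypoxia and 5 after hypobaric hypoxia followed by photobiomodulation. Per the labels' protocols, RNA was harvested with TRIzol and libraries were made from 1.4 ug of total RNA with the VAHTS Universal V10 kit. Whether this chemistry kept the strand is not given in the sources used here. Per the submitters' processing notes, fastp 1.0, HISAT2 and HTSeq were used with the genome build GRCm39. The order and settings of these tools and the annotation release are not given in the sources used here.

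One deposited table lists 15914 protein-coding genes. Although it is named as raw counts, none of its columns holds whole-number counts. Per the file headers, the authors computed an FPKM value for each gene in each library, with no pooling of replicates. Per the file headers, the authors also gave each gene's group mean as a signal, which is the read count divided by DESeq2 size factors and averaged over the libraries of a group. The authors deposited a linear fold change of the laser group over the hypoxia group per gene. They also deposited its log2 fold change, per the file headers. The deposited p-value and q-value belong to the authors' own comparison. The q-value equals the Benjamini-Hochberg adjustment of the p-value over the listed genes to within 4.38e-15. What filter chose the listed genes is not given in the sources used here. The authors' comparison is quoted only where "the authors' deposited table" is named.

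The group and replicate number of each library were taken from its labels. Because the values were FPKM and not counts, the planned count test was replaced by the test that had been fixed for that case, limma-trend (limma 3.58.1 in R 4.3.3) on log2(FPKM + 1), with the group as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, with no fold minimum. Genes were tested when they had at least 0.1 FPKM in at least 5 libraries, which left 14406. Log2 fold changes are hypoxia + PBM over hypoxia on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. Means ± SD are of FPKM over the 5 libraries of a group. The test, the pseudocount of 1, the gene lists, the rule for named genes and part of the alternatives were fixed before the data were examined. The FPKM minimum was chosen after the table, with the authors' p-values and q-values, had been viewed, but before any fit. It was the only minimum used for the main result. On data simulated for this comparison with 14434 genes, the script recovered 43% of genes changed 1.3-fold and 99% of those changed 2-fold. Of its 153 calls there, 11 were false (7.19%). The simulation gave every gene the same spread between libraries (dispersion 0.01) with independent noise, and changed only well-counted genes. These rates need not hold for genes with few reads or for genes that vary together.

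Whole reads were recovered by solving the FPKM columns against the authors' group means, since a gene's FPKM is its reads divided by a length and a library total. All values (100%) came out whole within a tolerance of 0.01 reads, with a largest distance from a whole number of 1.76e-07. These reads served for library depth, for shares of reads, for the mean log2 CPM used in the naming rule, for covariates and for alternatives with limma-voom, and never for the main test. Library totals ranged from 29283937 to 35957148 reads. They are sums over the listed protein-coding genes, so reads outside these genes are not included. Shares of reads were compared by a two-sided exact permutation test over all 252 assignments (scipy 1.17.1), with Benjamini-Hochberg adjustment over the 5 measures. Counting error is small at this depth for the genes named at several FPKM, and wider for those near the minimum. No 2 libraries of a group agreed within counting noise: the chi-square per gene between pairs lay between 5.97 and 13.8, so each library was counted once.

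Gene lists for pathways, cell types and neighbouring tissues were tested by camera from limma with a preset correlation of 0.01, over 37 lists with at least 5 measured members. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were run beside it. With an estimated correlation 0 of the 37 lists passed, where the smallest unadjusted p was 0.00448 for HIF targets. By fry, 3 lists passed: HIF targets, clock genes and striatal markers. The list of nuclear-retained RNAs had 0 members in the table, which holds protein-coding genes. The mitochondrially encoded genes are listed without their usual prefix and were matched by that shorter symbol. The named genes were the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 1. Predicted genes without a proper symbol were passed over. To these were added the up to 4 members with the smallest p of each list, or 2 in lists without a called gene, and the sex-linked genes. A gene named outside this rule is said to have been named after its values were seen.

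The replicate numbers do not pair the samples by the labels, so no block entered the main fit. Alternatives fixed beforehand were other scalings of FPKM, other filters, limma-voom with sample quality weights, the replicate number as a block, marker means of striatum and oligodendrocytes as covariates, removal of mitochondrial and haemoglobin genes, other thresholds and leaving out each library. Added after seeing the data were pseudocounts of 0.1 and 0.5, limma-voom without weights, robust variances, the removal of each library's trend on gene length and GC content (loess span 0.4), the mean of 6 clock genes as covariate, annotation terms and the authors' deposited table. GC content came from a mouse reference of another build (GRCm38), matched by symbol for 96.8% of tested genes, and no coordinates were taken from it. Figures were drawn with matplotlib 3.10.9.

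Some single-gene results from the fixed lists are not reported here.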

Results

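Prefrontal cortex of wild-type C57BL/6J mice was profiled by bulk RNA sequencing in 10 libraries. In the hypoxia group, 5 libraries came from mice exposed to hypobaric hypoxia, the low oxygen that goes with reduced air pressure. In the group called hypoxia + PBM here, 5 libraries came from mice that received photobiomodulation, a treatment with light (laser light, by the group's label), after hypobaric hypoxia. Libraries from mice kept at normal pressure were not analysed here. The values therefore describe what differed with photobiomodulation and not what hypoxia changed. The labels do not say that each library came from its own animal, and p-values then measure only the spread between these libraries, which may be technical. Expression is given in FPKM (fragments per kilobase of transcript, scaled to the mapped reads of the library). Between 29283937 and 35957148 reads per library lay behind these values, with 31592517 ± 2161680 reads (SD, n = 5) in hypoxia and 33958275 ± 2003490 (SD, n = 5) in hypoxia + PBM. Mitochondrially encoded genes took 4.74% ± 0.133 of the reads in hypoxia and 4.63% ± 0.265 in hypoxia + PBM (SD, n = 5 each; adjusted p = 0.516, two-sided exact permutation test). Ribosomal protein genes took 1.79% ± 0.0975 and 1.68% ± 0.0681 (SD, n = 5 each; adjusted p = 0.397, same exact test). The haemoglobin share, the share of the 50 most counted genes and the number of genes with at least 10 reads did not pass the exact permutation test either, with adjusted p from 0.397 to 0.54. Of the Y-linked genes, Ddx3y (10.8 ± 0.832 and 9.73 ± 0.521 FPKM), Uty, Eif2s3y and Kdm5d were measured in both groups and none of these 4 passed the test between them.

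The comparison asked which genes differ in prefrontal cortex when photobiomodulation follows hypobaric hypoxia, in a study of synaptic plasticity deficits. Genes of striatal medium spiny neurons, the projection neurons of the striatum, were lower in hypoxia + PBM, with the enkephalin precursor Penk at 62.6 ± 16.5 against 148 ± 41.7 FPKM (SD, n = 5 each). The striatum is a neighbouring tissue, and the labels do not describe the dissection. The clock genes Per2 and Nr1d1 and the hypoxia-responsive glycolytic regulator Pfkfb3 were also lower. The muscle-type glycogen phosphorylase Pygm, which releases glucose units from glycogen, was higher, at 17.9 ± 0.666 against 12.3 ± 0.515 FPKM (SD, n = 5 each), as was the vascular peptide gene Apln. In all, 411 of 14406 tested genes passed a limma-trend test at an adjusted p under 0.05, of which 166 were higher and 245 lower in hypoxia + PBM. Most changes were small: the median absolute log2 fold change of the called genes was 0.27. A change of at least 1.5-fold on the log2(FPKM + 1) scale was reached by 3 of the higher genes (Apln, Cideb and Rpe65, the last named after its values were seen) and by 30 of the lower ones, and 9 of the lower genes fell by at least 2-fold. The libraries of the 2 groups did not overlap for 341 of the called genes, and for 5.53% of all tested genes against 0.794% by chance. In the authors' deposited table, 1019 genes had a q-value under 0.05, and 405 of the 411 genes called here were among them with the same direction. With the mean of the striatal markers as a covariate only Pygm and Sh2d3c (the latter named after its values were seen) were called, so that each other called gene named in the following paragraphs lost its call in that fit. The called genes kept a median 80.9% of their fold there and 389 of 411 kept their sign, while standard errors grew 1.85 times. That covariate itself separated the groups without overlap, so no fit with it can cleanly divide its part from that of the group. The count of called genes was lower by more than 1.5 times without hypoxia replicate 1 (189 genes), 2 (265) or 5 (196). The same held without hypoxia + PBM replicate 1 (209), 2 (266) or 3 (221).

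**Figure D1:**
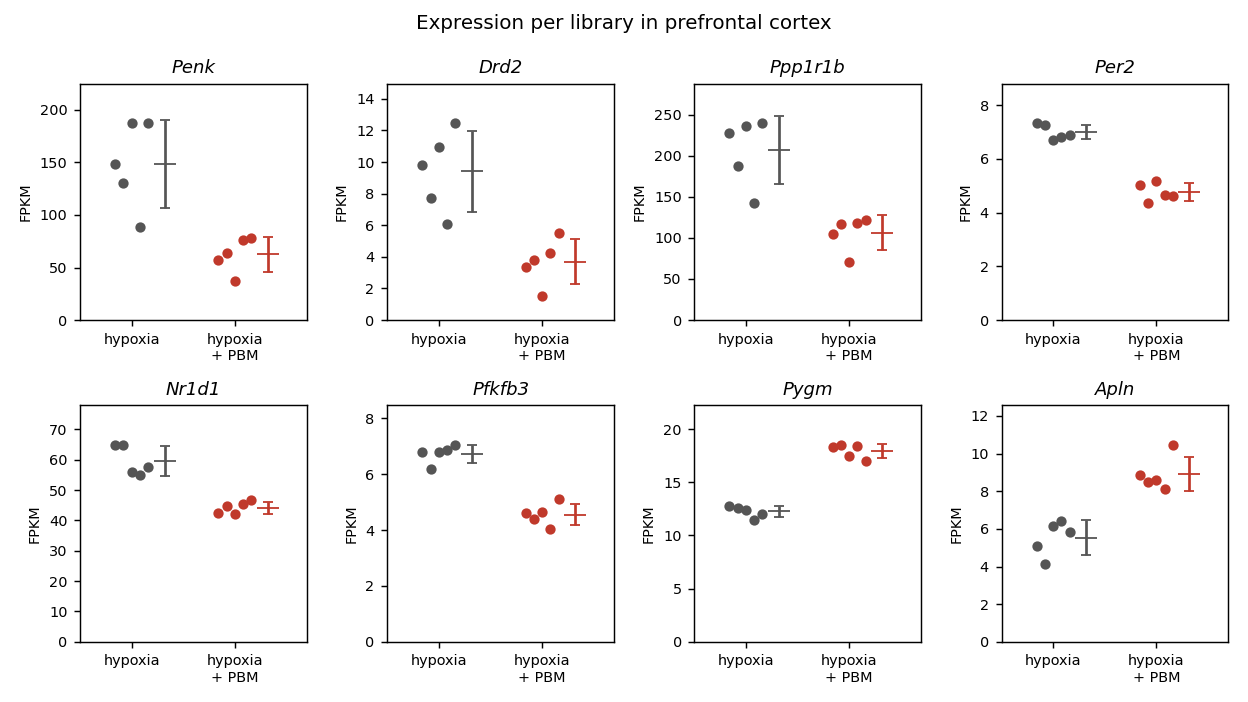
FPKM per library (vertical axes, each from 0) of 8 genes in hypoxia (grey points) and hypoxia + PBM (red points), with the mean and SD of the 5 libraries beside each group. Penk, Drd2, Ppp1r1b, Per2, Nr1d1 and Pfkfb3 lie lower and Pygm and Apln lie higher in every hypoxia + PBM library than in every hypoxia library.

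Striatal medium spiny neuron genes made up 8 of the 10 largest falls. Of the 17 measured markers of these neurons, 15 were lower in hypoxia + PBM and none was higher (16 lower when adjusted over the list alone). The list's median log2 change was -0.94 (camera adjusted p = 1.36e-17 with a preset correlation between genes). This list's adjusted p with an estimated correlation was 0.412. Different amounts of neighbouring striatum in the dissected pieces are a candidate explanation for these falls, which the labels cannot settle. Among the markers, receptors of the indirect pathway fell. The dopamine D2 receptor Drd2 went from 9.40 ± 2.55 to 3.69 ± 1.44 FPKM (SD, n = 5 each; log2 change -1.18 ± 0.22 SE, limma adjusted p = 0.0158), and the adenosine receptor gene Adora2a had a log2 change of -1.19 ± 0.25 (SE; limma adjusted p = 0.0259). Penk had a log2 change of -1.23 ± 0.22 (SE; limma adjusted p = 0.0124), and the orphan receptor Gpr6 had one of -1.10. Genes of the direct pathway fell as well. The dopamine D1 receptor Drd1 went from 10.6 ± 2.85 to 4.71 ± 1.36 FPKM (SD, n = 5 each; log2 change -1.03 ± 0.19 SE, limma adjusted p = 0.0152), and the substance P precursor Tac1 had a log2 change of -0.95. Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP-32, dropped from 207 ± 41.4 to 106 ± 21.1 FPKM (SD, n = 5 each; limma adjusted p = 0.0109). The developmental transcription factor Six3 had a log2 change of -0.88 and Syndig1l one of -1.19. Six3 was at a low level (1.99 ± 0.70 and 0.598 ± 0.199 FPKM, SD, n = 5 each), where the pseudocount of 1 understates the change. Outside the list, Rxrg (retinoid X receptor gamma, -1.21) and Lrrc10b (-1.16) completed the largest falls. Pdyn and Foxp1 were the list members that did not pass the test, with log2 changes of -0.061 ± 0.076 and -0.16 ± 0.06 (SE). Both were named after their values were seen. Of 11 thalamic and septal markers, 1 was higher (1 when adjusted over the list alone), the receptor-associated protein Ramp3 with 0.25, and the list's median was 0.094 (camera adjusted p = 0.042). With an estimated correlation this list's adjusted p was 0.537, and it lost its call in 5 of the 10 fits that left out 1 library (highest camera adjusted p = 0.319, without hypoxia + PBM replicate 3). The olfactory list did not pass camera (adjusted p = 0.305), although its member Pcp4l1 was lower, with -0.51. The mean of the 17 striatal markers spanned 3.28 to 4.01 log2(FPKM + 1) within hypoxia and 2.46 to 3.18 within hypoxia + PBM. Hypoxia + PBM replicate 3 lay apart from its group in Gpr6 and replicate 5 in Lrrc10b. Adora2a kept its call in 5 and Tac1 in 7 of the 10 fits that left out 1 library, with the highest limma adjusted p (0.0702 and 0.0521) without hypoxia replicate 5. Ramp3 kept its call in 2 of them (highest limma adjusted p = 0.0871, without hypoxia replicate 5) and lost it without a filter (0.055) and under limma-voom with quality weights (0.0521).

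The clock genes that fell were repressors and outputs of the circadian oscillator. Of 16 measured core clock and clock-output genes, 6 were lower and none was higher (8 lower and 1 higher when adjusted over the list alone). The median log2 change was -0.11 (camera adjusted p = 0.00018). Its adjusted p was 0.412 with an estimated correlation. Bhlhe41, a transcriptional repressor of the clock, went from 10.5 ± 0.847 to 7.07 ± 0.17 FPKM (SD, n = 5 each; log2 change -0.51 ± 0.051 SE, limma adjusted p = 0.000537). Per2, a core repressor of the oscillator, went from 7.01 ± 0.271 to 4.77 ± 0.338 FPKM (SD, n = 5 each; log2 change -0.47 ± 0.049 SE, limma adjusted p = 0.000751). Nr1d1, which encodes the nuclear receptor REV-ERB alpha, had a log2 change of -0.42 ± 0.052 (SE; limma adjusted p = 0.00264) and the cryptochrome Cry2 one of -0.25. All 6 of the called clock genes separated the groups with no overlap, as did 341 of all 411 called genes. Bmal1 and Clock, which drive the other arm of the oscillator, were at 0.069 ± 0.047 and 0.012 ± 0.055 (log2 change, SE), did not pass the test and were named after their values were seen. The calls of these 4 named clock genes held in each of the 10 fits that left out 1 library. The striatal marker mean fell by 0.81 log2 units in the same libraries (3.74 ± 0.297 in hypoxia and 2.93 ± 0.282 in hypoxia + PBM, SD, n = 5 each; exact permutation p = 0.00794, the smallest that 5 against 5 libraries allow). As a covariate the striatal marker mean was taken as log2 CPM of the recovered reads. With this covariate the mean log2 change of the 6 called clock genes was -0.303, against -0.383 without it. That of Per2 was -0.56 with the covariate (limma adjusted p = 0.0943).

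The list of hypoxia-inducible factor (HIF) targets was lower by camera with the preset correlation. Of 34 measured HIF targets, 25 had a negative change, and 5 were called lower and none higher (8 lower when adjusted over the list alone), with a median log2 change of -0.061 (camera adjusted p = 0.000415). The adjusted p of this list was 0.166 with an estimated correlation. Pfkfb3, which makes the activator of phosphofructokinase, went from 6.74 ± 0.322 to 4.55 ± 0.388 FPKM (SD, n = 5 each; log2 change -0.48 ± 0.055 SE, limma adjusted p = 0.00142). Bhlhe40, the close relative of Bhlhe41 and itself a clock repressor, had a log2 change of -0.45 ± 0.06 (SE; limma adjusted p = 0.00436). Ndrg1, a stress-induced gene that is also abundant in myelinating glia, had one of -0.35 and the histone demethylase Kdm3a one of -0.28. The MAX-interacting repressor Mxi1, named after its values were seen, had one of -0.26. Vegfa, the HIF target that drives vessel growth, was at 7.38 ± 0.258 and 6.90 ± 0.513 FPKM (SD, n = 5 each), did not pass the test (limma adjusted p = 0.358) and was also named after its values were seen. Pygm was the gene with the smallest p among those named by size, with a log2 change of 0.52 ± 0.039 (SE; limma adjusted p = 5.06e-05). Pygm and the first 4 HIF targets named kept their calls in each fit that left out 1 library. In the same libraries the striatal marker mean fell by 0.81 log2 units, and the medians of the microglia and oligodendrocyte lists were -0.083 and -0.051.

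Synaptic gene lists were higher by small amounts, by camera with the preset correlation only, and few of their members were called. Over 13938 genes the log2 change rose weakly with gene length (Spearman correlation 0.197). Of 40 postsynaptic glutamate receptor and scaffold genes, 30 had a positive change, but only 2 were called higher and 1 lower (5 and 1 when adjusted over the list alone). The median log2 change was 0.074 (camera adjusted p = 0.000445). An estimated correlation gave this list an adjusted p of 0.494. The scaffold Shank1 went from 24.5 ± 2.14 to 29.3 ± 1.71 FPKM (SD, n = 5 each; log2 change 0.25 ± 0.057 SE, limma adjusted p = 0.034). The scaffold Dlgap1 had a log2 change of 0.15, while the synaptic adhesion gene Lrrtm2 was lower, with -0.17. Of 39 presynaptic vesicle and release genes, 34 had a positive change and 1 was called, the vesicle fusion protein Vamp1 at 0.23 ± 0.049 (log2 change, SE; limma adjusted p = 0.0264; 3 higher when adjusted over the list alone). This list had a median of 0.068 (camera adjusted p = 4.01e-05). Under an estimated correlation the list's adjusted p was 0.494. Of 17 GABA receptor and inhibitory scaffold genes, 13 had a positive change. The list's median was 0.086 (camera adjusted p = 0.0076). With an estimated correlation this list's adjusted p was 0.494. Leaving out 1 library moved its median to between 0.0474 and 0.108, with a highest camera adjusted p of 0.0398 (without hypoxia + PBM replicate 1). Of 14 upper-layer excitatory neuron markers none was called (none when adjusted over the list alone), and Rorb and Rasgrf2 were at 0.2 each. The median of that list was 0.091 (camera adjusted p = 0.00794). Its adjusted p was 0.494 with an estimated correlation. The striatal marker mean fell by 0.81 log2 units in the same libraries. Taken as log2 CPM of the recovered reads, it ended all 4 list calls as a covariate. The camera adjusted p was then 0.581 for the postsynaptic, 0.584 for the presynaptic, 0.072 for the GABA receptor and 0.581 for the upper-layer list. Of the 10 fits that left out 1 library, Shank1 and Dlgap1 kept their calls in 3 each, with the highest limma adjusted p without hypoxia + PBM replicate 3 (0.083) and replicate 1 (0.101). Lrrtm2 kept its call in 2 (0.102) and Vamp1 in 4 (0.0722), both highest without hypoxia replicate 5. Dlgap1 also lost its call once the trend on gene length and GC content was removed, and Lrrtm2 under upper-quartile scaling.

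Several vascular and interferon genes were higher in hypoxia + PBM, and their lists passed camera with the preset correlation only. Apln, the precursor of the peptide apelin, went from 5.53 ± 0.936 to 8.91 ± 0.915 FPKM (SD, n = 5 each; log2 change 0.61 ± 0.095 SE, limma adjusted p = 0.00737). Edn1, which encodes the vasoconstrictor endothelin-1, had a log2 change of 0.54 at a low level (0.67 ± 0.255 and 1.42 ± 0.364 FPKM, SD, n = 5 each). Hypoxia + PBM replicate 3 lay apart from its group in Edn1. The growth factor midkine (Mdk) had a log2 change of 0.52 ± 0.06 (SE; limma adjusted p = 0.00142). Of 22 endothelial markers, 3 were higher and none was lower (5 and 1 when adjusted over the list alone), with a median of 0.13 (camera adjusted p = 0.000831). The adjusted p of this list was 0.494 with an estimated correlation. The tight-junction protein Cldn5 went from 11.3 ± 1.28 to 14.9 ± 1.36 FPKM (SD, n = 5 each; log2 change 0.37 ± 0.074 SE, limma adjusted p = 0.0185). Ly6c1, whose reads can be shared with its near-identical neighbours, had a log2 change of 0.39 and the angiopoietin receptor Tek one of 0.28. The 12 pericyte and smooth muscle markers had a median of 0.1 and the 17 meningeal fibroblast markers one of 0.053, with no called member (1 and 2 higher when adjusted over each list alone; camera adjusted p = 0.0322 for each). With an estimated correlation the adjusted p was 0.537 for each. The pericyte receptor Pdgfrb was at 0.19 and the collagen gene Col1a1 at 0.21. Of 23 interferon-stimulated genes, 2 were higher (4 when adjusted over the list alone), Xaf1 with 0.23 and the transcription factor Irf7 with 0.39. Xaf1 was at a low level (0.677 ± 0.0697 and 0.970 ± 0.0748 FPKM, SD, n = 5 each). The list's median was 0.16 (camera adjusted p = 0.00106). An estimated correlation gave this list an adjusted p of 0.494. Ifit3b, an interferon-induced gene outside the list that can share reads with its close copy Ifit3, had a log2 change of 0.44. Among the 10 largest rises were also Cideb (0.6), Pglyrp1 (0.51), the lipid carrier Pltp (0.49), Klhl34 (0.46) and the adhesion protein Kirrel2 (0.45). Apln, Mdk, Ifit3b and Cldn5 kept their calls in each fit that left out 1 library. Of those 10 fits, Xaf1 kept its call in 8, Edn1 in 7, Pglyrp1 and Ly6c1 in 6 and Cideb and Kirrel2 in 5, with highest limma adjusted p between 0.0524 and 0.0703. Pltp kept its call in 4, Tek and Irf7 in 3 and Klhl34 in 2, with highest limma adjusted p between 0.0652 and 0.0979. The highest values came without hypoxia replicate 1 for Edn1 and Cideb, without hypoxia replicate 5 for Klhl34, and without hypoxia + PBM replicate 1 or 3 for the other 7. The pericyte and meningeal lists kept their calls in 6 of these fits each, with the highest camera adjusted p (0.196 and 0.173) without hypoxia replicate 2. With the striatal marker mean as covariate the endothelial list did not pass camera (adjusted p = 0.338).

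The lists of microglia and of oligodendrocyte markers were lower by camera with the preset correlation only, with few called members. Of 19 microglia markers, 2 were lower (3 when adjusted over the list alone). The lysosomal protease gene Ctss went from 83.1 ± 5.97 to 65.3 ± 5.61 FPKM (SD, n = 5 each; log2 change -0.35 ± 0.062 SE, limma adjusted p = 0.0138). The lipid receptor Trem2 had a log2 change of -0.31. The list's median was -0.083 (camera adjusted p = 0.0033). With an estimated correlation this list's adjusted p was 0.537, and hypoxia replicate 3 stood apart at the high end of its group. Of 20 oligodendrocyte markers, 1 was lower (2 when adjusted over the list alone), the fatty acid hydroxylase Fa2h at -0.26. The list's median was -0.051 (camera adjusted p = 0.0322), and its adjusted p was 0.537 with an estimated correlation. The myelin protein gene Mbp was at -0.13 without passing the test. Of 20 astrocyte markers, 3 were higher (6 higher and 4 lower when adjusted over the list alone), although the list did not pass camera (adjusted p = 0.122). The folate enzyme Aldh1l1 had a log2 change of 0.27 ± 0.037 (SE; limma adjusted p = 0.00481), the bicarbonate transporter Slc4a4 one of 0.28 and the glutamate transporter Slc1a2 one of 0.21. Among oligodendrocyte precursor markers the proteoglycan Cspg4 was higher, with 0.34, and the list did not pass camera (adjusted p = 0.369). Cspg4 was at a low level (0.912 ± 0.135 and 1.43 ± 0.231 FPKM, SD, n = 5 each). Without hypoxia replicate 3 the microglia list lost its call (camera adjusted p = 0.0897), and its median lay between -0.15 and -0.0455 over all fits that left out 1 library. The microglia call also ended with the oligodendrocyte marker mean as covariate. The oligodendrocyte list lost its call once the trend on gene length and GC content was removed (camera adjusted p = 0.0521). It also lost it without hypoxia replicate 1 (0.0865), 3 (0.145) or 4 (0.191) and without hypoxia + PBM replicate 3 (0.0948) or 4 (0.129). Trem2 kept its call in 4 of the 10 fits that left out 1 library, Fa2h and Slc1a2 in 5 and Cspg4 in 9. The highest limma adjusted p was 0.0684 for Trem2 (without hypoxia replicate 5), 0.0609 for Slc1a2 (without hypoxia replicate 1), and 0.0681 for Fa2h and 0.0579 for Cspg4 (without hypoxia + PBM replicate 1). The striatal marker mean fell by 0.81 log2 units in the same libraries. With that mean, taken as log2 CPM of the recovered reads, as a covariate the microglia median was 0.046 (camera adjusted p = 0.345).

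Nuclear genes of the respiratory chain and cytosolic ribosomal protein genes were lower by small amounts as lists, by camera with the preset correlation only. Cytochrome c oxidase is the enzyme complex thought to absorb red and near-infrared light in photobiomodulation. Of its 14 nuclear genes (cytochrome c included), 12 had a negative change and none was called (none when adjusted over the list alone). Their median was -0.086 (camera adjusted p = 0.0076). Under an estimated correlation the list's adjusted p was 0.537. Cox6c was at 516 ± 30.1 and 464 ± 36.4 FPKM (SD, n = 5 each). Of 63 other respiratory chain and ATP synthase genes, 55 had a negative change and none was called (none when adjusted over the list alone). Their median was -0.055 (camera adjusted p = 0.00018). This list's adjusted p with an estimated correlation was 0.537. The 13 mitochondrially encoded genes had a median of -0.029 and did not pass camera (adjusted p = 0.614). Of 84 ribosomal protein genes, 82 had a negative change and 1 was called, Rps27 at -0.18 (none when adjusted over the list alone), whose reads can be shared with pseudogene copies. The median of that list was -0.096 (camera adjusted p = 4.68e-14). Its adjusted p was 0.494 with an estimated correlation. Of 24 antioxidant and NRF2-responsive genes, 1 was lower (6 when adjusted over the list alone). The thioredoxin reductase Txnrd1 went from 17.3 ± 0.827 to 14.6 ± 0.637 FPKM (SD, n = 5 each; log2 change -0.23 ± 0.042 SE, limma adjusted p = 0.0147). The list's median was -0.09 (camera adjusted p = 0.000276). The adjusted p of this list was 0.494 with an estimated correlation. Of 19 glucocorticoid-responsive genes 1 was lower (2 when adjusted over the list alone), the pyruvate dehydrogenase kinase Pdk4 at -0.37. The median of these genes was -0.11 (camera adjusted p = 0.042). An estimated correlation gave this list an adjusted p of 0.537. With the striatal marker mean as covariate, the median was 0.046 for cytochrome c oxidase (camera adjusted p = 0.441) and 0.016 for ribosomal proteins (0.338). In the same fit it was 0.041 for the other respiratory genes (camera adjusted p = 0.00929) and 0.19 for the mitochondrially encoded genes (1.09e-05), both then called higher. The covariate itself separated the groups without overlap, so these calls cannot be read as a rise with photobiomodulation. The call of the other respiratory genes ended once the trend on gene length and GC content was removed (camera adjusted p = 0.103). Without hypoxia + PBM replicate 3 the cytochrome c oxidase list lost its call (camera adjusted p = 0.0814). Leaving out 1 library moved the median to between -0.0689 and -0.0295 for the other respiratory genes, -0.106 and -0.0599 for the antioxidant genes and -0.165 and -0.0454 for the glucocorticoid genes. Of the 10 fits that left out 1 library, the glucocorticoid list kept its call in 6 (highest camera adjusted p = 0.457, without hypoxia + PBM replicate 5). Rps27 kept its call in 3 (highest limma adjusted p = 0.0905, without hypoxia + PBM replicate 1) and Pdk4 in 7 (0.0553, without hypoxia replicate 1).

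**Figure D2:**
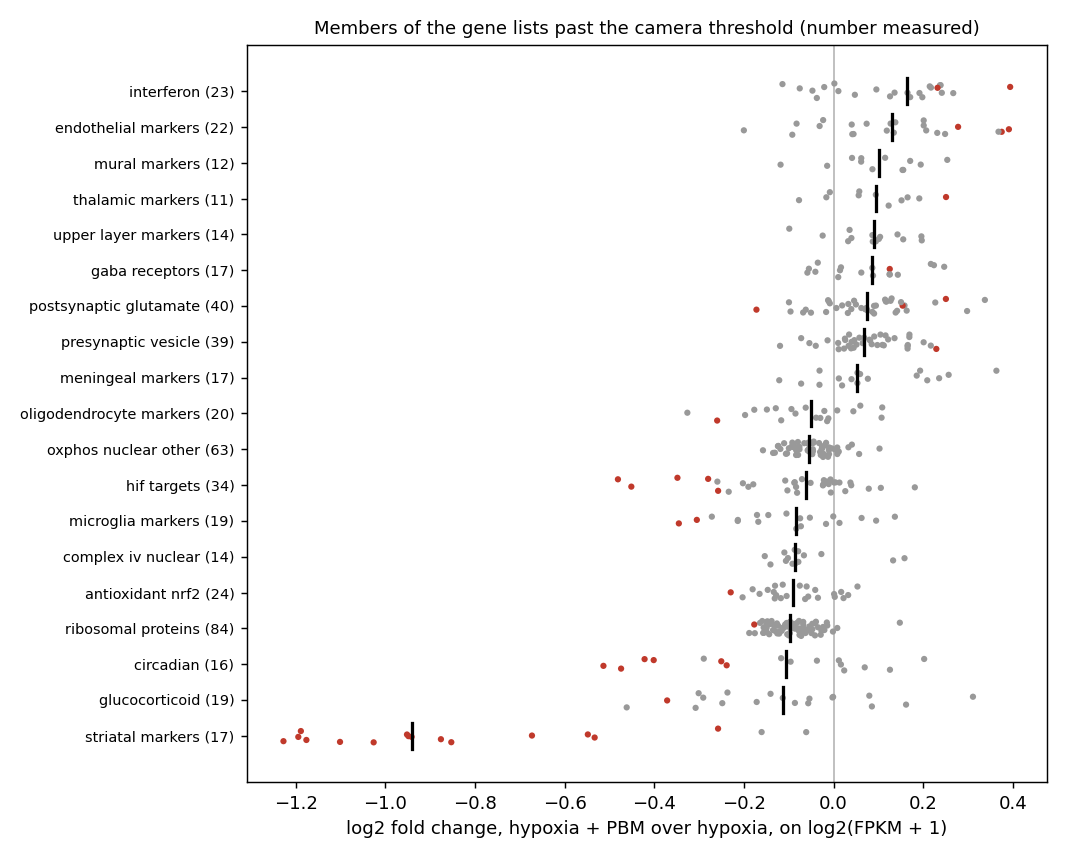
Log2 fold change of each measured member (points, horizontal axis; hypoxia + PBM over hypoxia on log2(FPKM + 1)) of the 19 gene lists that passed camera, with called genes in red and the list median as a black bar. The striatal markers reach a median of -0.94, while the other 18 medians lie between -0.11 and 0.16.

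Stress and signalling lists had few called members and did not pass camera, which misses lists whose members move both ways. The mixed form of fry counts change in either direction, without weighing a list against other genes. Its adjusted p was 1.42e-09 for immediate-early, 1.11e-06 for unfolded-protein and 0.000307 for cell-death genes. It lay between 0.00154 and 0.0354 for the deep-layer, heat-shock, monoamine and acetylcholine receptor and perineuronal net lists, and was 0.504 for cytokine and reactive-glia genes. Of 34 immediate-early genes, 1 was higher and 2 were lower (8 and 9 when adjusted over the list alone). The pseudokinase Trib1 was at 0.29 ± 0.057, Ier5 at -0.28 ± 0.041 and the transcription factor Egr1 at -0.38 ± 0.083 (log2 change, SE; limma adjusted p = 0.0175, 0.00541 and 0.0284; camera adjusted p = 0.647). The deep-layer cortical marker Syt6 was lower, from 4.18 ± 0.425 to 2.80 ± 0.278 FPKM (SD, n = 5 each; limma adjusted p = 0.00669). It was the only called gene of 18 in its list (2 higher and 5 lower when adjusted over the list alone; camera adjusted p = 0.129). Herpud1 of the unfolded-protein response was at -0.26 (1 higher and 6 lower of 22 when adjusted over the list alone; camera adjusted p = 0.199) and the chaperone Dnajb4 at -0.2 (1 of 19; camera adjusted p = 0.184). The muscarinic receptor Chrm3 (0.31) and the beta-1 adrenergic receptor Adrb1 (0.25) were higher among 24 monoamine and acetylcholine receptors (2 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.126). The link protein Hapln1 was higher (0.28) among 11 perineuronal net genes (1 when adjusted over the list alone; camera adjusted p = 0.0919). The list of 18 cell-death genes did not pass either (camera adjusted p = 0.164). Cytokine and reactive-glia genes had no called member of 21 (camera adjusted p = 0.188). Dnajb4 and Hapln1 kept their calls in 7 of the 10 fits that left out 1 library, Chrm3 in 5, Egr1 in 4 and Adrb1 in 2. The highest limma adjusted p came without hypoxia replicate 5 for Dnajb4 (0.0567), Hapln1 (0.0593) and Egr1 (0.0731) and without hypoxia replicate 1 for Adrb1 (0.0649). It came without hypoxia + PBM replicate 1 for Chrm3 (0.0629).

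**Figure D3:**
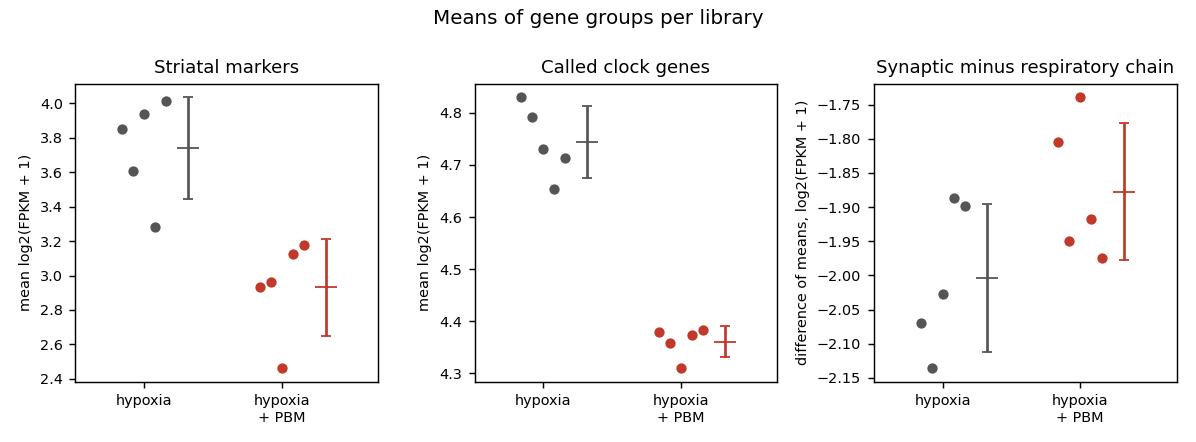
Mean log2(FPKM + 1) per library of the 17 striatal markers (left) and of the 6 called clock genes (middle), and the synaptic mean minus the respiratory-chain mean (right), for hypoxia (grey) and hypoxia + PBM (red) with the mean and SD of 5 libraries. The groups do not overlap in the first pair of panels, whereas in the right panel 2 of the 5 hypoxia + PBM libraries lie above every hypoxia library and the exact permutation p is 0.0952.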

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

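A library was set apart from the other 4 of its group when its gap to the nearest of them, divided by the group's range, exceeded 0.71. This was looked at in 124 groups of 5 values (lists, shares and the 20 genes named by size), and 9 stood apart against 6.2 expected by chance, so single cases carry little weight. Hypoxia replicate 3 was high in the microglia markers, with a mean of 4.15 log2(FPKM + 1) against 3.92 to 3.97 in the others, and in the oligodendrocyte precursor markers, with 2.61 against 2.52 to 2.53. Hypoxia replicate 5 was high in the neurotrophin and CREB list, at 3.54 against 3.44 to 3.47. Hypoxia + PBM replicate 1 was high in the blood markers, at 1.79 against 0.667 to 0.969, and in the share of reads from haemoglobin genes, at 0.00181% against 0.000275% to 0.000573%. Hypoxia + PBM replicate 5 had 5.09% of its reads from mitochondrially encoded genes, against 4.40% to 4.57%, and 16.3 FPKM of Lrrc10b, against 7.18 to 9.79. Hypoxia + PBM replicate 3 was low in Gpr6, at 0.986 FPKM against 2.57 to 3.15, and high in Edn1, at 2.057 FPKM against 1.195 to 1.366.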

How the results depend on the processing

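The pseudocounts, limma-voom without weights, robust variances, length and GC removal, the clock covariate and the authors' deposited table were chosen after seeing the data. Under other scalings of FPKM, other filters, other pseudocounts, robust variances and removal of mitochondrial and haemoglobin genes, the count of called genes stayed between 358 and 448 (411 in the report), and no called gene named by the rule changed direction. Among named genes, calls ended with no filter on low values for Klhl34 (limma adjusted p = 0.0597), Irf7, Tek and Ramp3, under upper-quartile scaling for Lrrtm2 (0.0618) and Rps27 (0.0504), and with robust variances for Adora2a (0.0635). Upper-quartile scaling gave 213 higher and 215 lower genes. limma-voom on recovered reads called 577 genes (268 higher), and with sample quality weights 616 (281 higher). Removing the length and GC trend gave 654 (291 higher, 363 lower), and the table deposited by the authors called 1019 genes (480 higher, 539 lower). Length and GC removal ended the call of Dlgap1 (limma adjusted p = 0.107), and voom quality weights that of the mural list (camera adjusted p = 0.0521). Stricter thresholds left 9 genes at 2-fold and 33 at 1.5-fold, and an unadjusted p with 1.5-fold also left 33. In the authors' table, whose folds carry no pseudocount of 1 FPKM, p under 0.05 with 1.5-fold gave 155 higher and 166 lower genes. The cause of these differences was not tested, apart from the fold minimum added to the adjusted p, which keeps fewer genes by construction. Of the 37 lists, 19 passed camera, 3 passed fry and 0 passed camera with an estimated correlation. Thalamic markers were past the threshold in the report but not under upper-quartile scaling (camera adjusted p = 0.0631), no filter (0.0623), limma-voom (0.0585), its quality weights (0.0821), length and GC removal (0.0973) or the oligodendrocyte covariate (0.0512). The planned TMM scaling, Wald test, robust dispersion test and surrogate variable were meant for deposited counts and were not run on the recovered reads, which served limma-voom only among the tests, and total-count scaling is that of FPKM itself.

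The replicate number as a replicate block gave 256 genes (105 higher, 151 lower), 221 of them among the 411, and all 19 lists. It ended the calls of 16 of the 61 called named genes, among them Adora2a, Cideb, Pglyrp1, Pltp, Shank1, Dlgap1, Lrrtm2, Ly6c1, Tek, Xaf1, Fa2h, Hapln1, Rps27 and Ramp3 (limma adjusted p between 0.0543 and 0.0976). Same-numbered libraries correlated between -0.072 and 0.205 in their deviations, and 1 of 5 hypoxia libraries correlated best with its own number, so the numbers are not treated as pairs.

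Leaving out 1 library gave between 189 and 538 called genes (higher 73 to 203, lower 116 to 335). The list calls numbered between 16 and 19. Medians moved by more than 1.5 times also for complex IV (-0.106 to -0.0553), oligodendrocyte (-0.0844 to -0.0268), mural (0.0571 to 0.141), meningeal (0.0299 to 0.0873) and thalamic markers (0.0339 to 0.144). The shares of reads and numbers of detected genes stayed short of the threshold in each such fit and at other cut-offs, and the sign of the haemoglobin difference turned without hypoxia + PBM replicate 1.

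With the striatal marker mean as covariate 2 genes were called (2 higher, 0 lower) and 7 lists: HIF targets, clock, glucocorticoid and interferon genes as before, choroid plexus markers lower, and mitochondrially encoded and other respiratory genes higher. Called genes kept a median 80.9% of their fold while standard errors grew 1.85 times, and 389 of 411 kept their sign, so the calls ended mainly through the larger errors. For the striatal genes the covariate removes the change by construction: Adora2a was at 0.18, Drd2 at 0.026, Drd1 at 0.0084, Tac1 at 0.052 and the list's median at 0.00034. Medians also reversed for upper-layer (-0.0017), thalamic (-0.039), microglia (0.046), mural (-0.015), mitochondrially encoded (0.19), complex IV (0.046), other respiratory (0.041) and ribosomal protein genes (0.016), and the cause was not tested. The striatal covariate separated the groups without overlap, so these reversals cannot be read as changes in the other direction. The oligodendrocyte covariate left 313 calls. It ended the list calls of complex IV (camera adjusted p = 0.0514), microglia (0.0955) and oligodendrocytes themselves (0.659). Adora2a, Edn1, Kirrel2, Pglyrp1, Dlgap1, Lrrtm2, Vamp1, Ramp3, Cspg4, Tek, Adrb1, Irf7 and Rps27 were among the named genes that lost their calls, with limma adjusted p between 0.0502 and 0.0782.

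With the mean of 6 clock genes as covariate 0 genes were called by limma (0 higher, 0 lower). That mean nearly equals the group: standard errors grew 4.3 times, 31% of the fold was kept and 258 of 411 genes kept their sign, so these values say little. Reversed log2 changes of rises were Apln -0.17, Edn1 -0.84, Pglyrp1 -0.48, Pltp -0.51, Shank1 -0.2049, Vamp1 -0.029, Slc4a4 -0.23, Slc1a2 -0.18, Cspg4 -0.026, Cldn5 -0.27, Ly6c1 -0.43, Chrm3 -0.1952 and Irf7 -0.00044. Those of falls were Penk 0.17, Rxrg 0.24, Syndig1l 0.38, Adora2a 0.18, Drd2 0.12, Lrrc10b 0.01002, Gpr6 0.41, Drd1 0.25, Ppp1r1b 0.33, Tac1 0.62, Six3 0.42, Pcp4l1 0.12, Ctss 0.15, Trem2 0.12, Dnajb4 0.045, Herpud1 0.051, Pdk4 0.14, Bhlhe41 0.016, Nr1d1 0.19 and Cry2 0.0093. Reversed medians were postsynaptic -0.23, presynaptic -0.14, GABA receptors -0.11, upper-layer -0.036, thalamic -0.19, endothelial -0.34, mural -0.53, neurotrophin -0.13 and neuromodulator receptors -0.21. The others were striatal 0.23, oligodendrocyte 0.059, mitochondrially encoded 0.23, complex IV 0.25, other respiratory 0.29, antioxidant 0.22, glucocorticoid 0.28 and ribosomal proteins 0.31.

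Small changes are the most easily missed. In data simulated with 5 libraries per group, 43% of 1.3-fold and 99% of 2-fold changes were recovered. The changed genes there were well counted and their noise was independent, so these rates need not hold for genes with few reads. Depth was not set against the spread between libraries, so which of them limits recovery is not tested. A gene without a call is not shown to be equal between the groups.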

Other observations

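Of the tests in this part, the annotation terms, the correlation between striatal markers, the change of direct-pathway genes, the change of the opposite-phase clock genes and the separate look at the respiratory chain outside complex IV were chosen only after the results they bear on had been seen. Removal of the length and GC trend, used here on 5 lists, was also added after seeing the data. Among 2601 annotation terms, 53 passed camera with the preset correlation, 22 higher and 31 lower in hypoxia + PBM, and 0 passed with an estimated correlation (adjusted p = 0.997 for each of the 53). The lower terms were led by the ribosome and also held the proteasome (44 genes, camera adjusted p = 0.000115). The higher terms included inhibitory synapse assembly (11 genes, camera adjusted p = 0.000946), homophilic cell adhesion (68 genes, 0.00123) and acetylcholine receptor signaling (14 genes, 0.00174). By fry, 2 terms passed, neither of them among the 53.

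Several genes with small p-values lay outside the fixed lists and were picked out after their values were seen. Slc25a18, a mitochondrial glutamate carrier, went from 22.4 ± 1.03 to 15.3 ± 0.491 FPKM (SD, n = 5 each; limma adjusted p = 5.06e-05), and Hs3st1, a heparan sulfate sulfotransferase, had a log2 change of 0.39 ± 0.038 (SE; limma adjusted p = 0.000537). The stress-induced gene Nupr1 had a log2 change of -0.84 ± 0.097 (SE) and the presynaptic glutamate receptor gene Grm2 one of 0.41 ± 0.061. Of the fixed lists not described so far, none passed camera. Cortical interneuron markers had a median log2 change of 0.028 (camera adjusted p = 0.239), with Dlx5 at -0.39 and Lamp5 at 0.22, neither called. Choroid plexus markers had a median of -0.16 (camera adjusted p = 0.0919), blood markers one of 0.1 (0.819), mitochondrial biogenesis and dynamics genes one of -0.012 (0.599) and opsins and light- or heat-responsive channels one of 0.094 (0.0965). Neurotrophin and CREB signalling genes had a median of 0.00062, a mean of -0.0072 and a camera direction of lower (adjusted p = 0.834). By the mixed form of fry, which counts change in either direction, this list had an adjusted p of 3.69e-05 and the interneuron list 0.00186. Choroid plexus (0.533) and blood markers (0.721) did not pass the mixed form.

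The fall of the striatal markers involved their most abundant transcripts, with Ppp1r1b at 207 and 106 FPKM and Penk at 148 and 62.6 FPKM in hypoxia and hypoxia + PBM. A change in indirect-pathway neurons alone is argued against by the fall of the direct-pathway genes Drd1 (log2 change -1.03) and Tac1 (-0.95). Both had been seen among the largest falls before this was asked. The mean log2 change of Drd1, Tac1, Pdyn and Isl1 was -0.573 ± 0.131 (SE), with Pdyn hardly changed. That of Drd2, Adora2a, Penk and Gpr6 was -1.17 ± 0.274 (SE). Different amounts of neighbouring striatum in the dissected pieces are a candidate explanation. Within the groups the 17 markers rose and fell together, with a mean pairwise correlation of 0.734. The highest value among 1000 random gene sets of matched level was 0.145. Random genes are a weak yardstick: the estimated correlation was 0.905 for choroid plexus markers and 0.7 for ribosomal proteins, though 0.0108 for HIF targets. A change within the neurons could also move their markers together, so the correlation cannot tell these explanations apart. All 17 were measured in these cortex libraries, cortex itself expresses several of them, and Pdyn was at -0.061 ± 0.076 (log2 change, SE). The labels do not describe the dissection, and an effect of photobiomodulation on such neurons was not tested and stays open.

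The 6 called clock genes had a mean log2 change of -0.383 ± 0.034 (SE) and did not overlap between the groups (exact permutation p = 0.00794, the smallest that 5 against 5 libraries allow). They were averaged because they had been called, so that p is not a separate test. With the striatal marker mean as covariate their mean was still -0.303 ± 0.056 (SE). Single clock genes lost their calls as standard errors grew, and the clock and striatal means correlated at 0.542 within the groups. Whether neighbouring striatum is their whole cause cannot be decided by this fit. The genes were chosen by their calls, and the striatal marker mean, an imprecise measure of striatal tissue, itself separated the groups without overlap. Collection of the groups at different times of day may also lower these genes: Bmal1, Clock, Npas2 and Nfil3, which peak opposite to Per2 and Nr1d1, had a mean change of 0.042 ± 0.035 (SE; exact permutation p = 0.246). Time of day and photobiomodulation cannot be told apart for these genes, since the labels give no collection time and the opposite-phase genes moved too little to decide.

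The synaptic lists were higher and the respiratory-chain lists lower by small amounts, by camera with the preset correlation only: none of the 5 passed with an estimated correlation (adjusted p between 0.494 and 0.537) or by fry (0.126 to 0.306). Once a trend on gene length and GC content was removed, the median went from 0.074 to 0.071 for the postsynaptic list. It went from 0.068 to 0.054 for the presynaptic and from 0.086 to 0.077 for the GABA receptor list. The trend is thus argued against as the whole cause of these medians. With the preset correlation 4 of the 5 lists stayed past the threshold, which decides little as none passed with an estimated one. The complex IV median shrank from -0.086 to -0.0536 (camera adjusted p = 0.0333). For the respiratory chain outside complex IV the trend stays open, because the median then went from -0.055 to -0.0255 (camera adjusted p = 0.103). Variation between libraries within both groups may account for the pattern: the synaptic mean minus the respiratory mean was -2.004 ± 0.109 in hypoxia and -1.877 ± 0.101 in hypoxia + PBM (log2 units, SD, n = 5 each; exact permutation p = 0.0952). An effect of photobiomodulation stays open as well.

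Of 100 splits of the 10 libraries into groups of 5 against 5, only 1, the real one, called as many as 411 genes, and the highest of the others called 2. Chance assignment of libraries to groups is therefore argued against as the source of the count, though not excluded. The other splits mix the groups, so any difference between the groups widens their spread and lowers their counts.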
